A study of Homo sapiens with 42 samples.

How the data were processed

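RNA abundance was measured by polyadenylated RNA sequencing of peripheral blood mononuclear cells from 7 healthy donors, 5 patients with uncomplicated CVID and 9 with complicated CVID, each cultured for 18 h in medium and with LPS. The deposited files held raw read counts per gene, which the authors made by aligning reads to GRCh38.p10 with STAR 2.6.1 and counting them with HTSeq 0.11.0. No reads were realigned here. Each file held 58233 gene identifiers, of which 57895 were given symbols and coordinates from GENCODE 29 and 338 had no symbol. The strand of the libraries was not given in the sources used here. HTSeq's ambiguous reads amounted to 12.7% to 15.0% of the reads in its file (median 13.3%), reads without a feature to 1.17% to 2.55% and alignments that were not unique to 3.54% to 8.18%. Reads of immunoglobulin and T cell receptor paralogs are hard to place, so that values of their single genes are uncertain.

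Groups were taken from the labels, as class of donor by culture, with donor number as the replicate. The sequencing run was read from the deposited files' names. The labels' statement of a single batch was not relied on, since run explained 64.5% of the spread along the fourth principal component, which held 6.4% of the variance. In the 519 sex-linked genes, 0 of 21 donors had 2 libraries that disagreed, and these genes were then left out. The 2 libraries of a donor were checked by correlating their deviations from the group and run means: the median r over 21 pairs was 0.421 (-0.057 to 0.745), against -0.071 with other donors' libraries, and 19 of 21 donors matched their own library best. Donors of the same number in different classes had median r of -0.003 to 0.114, so numbers paired nothing across classes. Among 134 pairs of libraries of the same group 0 lay within counting noise, the lowest chi-square per degree of freedom being 3.42.

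Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8). Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Genes were kept by filterByExpr, leaving 16783, and libraries were scaled by TMM. Quasi-likelihood models held a mean for each of the 6 groups and a term for the run, over all 42 libraries, with 12 comparisons: the 3 classes against each other in medium and with LPS, LPS against medium in each class, and the differences of these responses. P values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a limit of 0.05. The common biological coefficient of variation was 0.348 with 34 residual degrees of freedom, 0.341 with 10 when complicated and uncomplicated CVID with LPS were fitted alone, and 0.355 with 12 for complicated CVID and healthy donors in medium alone. The 2 libraries of a donor entered the main fit as independent, although their consensus correlation was 0.509. The 34 degrees of freedom thus count libraries rather than donors, and LPS values ignore the pairing except where a donor block or a donor random effect is named. A prior count of 2 was used for log2 CPM. No scaling moved the median of all genes by over 0.1 on the log2 scale.

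The 31 gene lists, the comparisons and the alternatives were written down before the data were examined. Lists were tested with limma's camera with a preset correlation between genes of 0.01, and again with an estimated correlation, and adjusted over the 31 lists of each comparison. Calls within a list were also counted with p adjusted over the list alone. Immunoglobulin segments and families of ribosomal, respiratory chain, chaperonin and proteasome genes were added after the data were seen. Genes named first in each comparison were, by a fixed rule, the 10 with the smallest p in each direction that passed the test with a log2 fold change of at least 1 in size, or of any size where fewer than 5 had that, among protein-coding and receptor constant genes with a symbol. Other genes were taken from the lists, and some genes are not reported here. The direction in donors was counted for LPS as donors whose LPS value lay on that side of their medium value, and between classes as patients past the other class's median.

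Alternatives were scaling by RLE, no filter beyond 1 count, no run term, only the groups compared, each donor left out in turn, each run alone where it held both classes, the donor as a block for LPS, the replicate number as a block between classes, the DESeq2 Wald test and limma voom with donor as a random effect (consensus correlation 0.509). Leaving out the 4 shallowest libraries was added after the data were seen.

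The procedure was tested on simulated data with the depths and dispersions of the real libraries. In these data 200 genes changed, 100 by 2-fold and 100 by 4-fold. They held no run effect and no donor effect, and genes were drawn independently. The shares below therefore do not cover the correlation between a donor's 2 libraries. Against healthy donors in medium, 56% and 74% were recovered for complicated and 38% and 63% for uncomplicated CVID, and 45% and 76% between the patient classes. With LPS the shares were 48% and 77%, 38% and 69%, and 47% and 78%. For LPS against medium they were 52% and 74% in healthy donors, 57% and 77% in uncomplicated and 56% and 90% in complicated CVID. For the differences of responses they were 42% and 66%, 20% and 58%, and 25% and 60%. False calls made up 1.6% to 8.6% of the calls. A list raised on purpose had an adjusted p of 1.78e-40 by camera with the preset correlation, and 0 of 30 random lists were called. The simulated genes were uncorrelated, so this says nothing about false list calls among correlated genes.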

Results

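Peripheral blood mononuclear cells, the lymphocytes, monocytes and dendritic cells of blood, were taken from 21 donors and cultured for 18 h in medium alone or with lipopolysaccharide (LPS). LPS is a component of the bacterial outer membrane that activates monocytes through CD14 and TLR4. The donors were 7 healthy donors, 5 patients with uncomplicated common variable immunodeficiency (CVID) and 9 patients with complicated CVID. CVID is a disorder with low serum immunoglobulin and poor antibody responses, and its complicated form adds inflammatory disease. Each donor gave 2 libraries of polyadenylated RNA, 42 in all, so that class of donor and culture formed 6 groups. The question set by the series is how cytokine disturbance and antibody deficiency meet in patients with inflammatory complications.

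Counts assigned to genes ranged from 586144 to 22477243 per library, with a median of 16949897.5. In medium, the median total was 16530165 in healthy donors (3870000 to 20072287), 19385756 in uncomplicated CVID (16267657 to 20633004) and 16576574 in complicated CVID (1923282 to 20348098). With LPS, the medians were 8290030 (586144 to 18486963), 18303484 (11252531 to 22477243) and 16945857 (1104457 to 18600089). The names of the deposited data put the libraries into 3 sets, taken here as sequencing runs. The labels state a single batch, and whether the sets are runs was not settled. Run 1 held healthy donors 1, 2 and 3 with complicated CVID 1, 2 and 4, run 2 all uncomplicated CVID with complicated CVID 3, 7, 8 and 9, and run 3 the others. Run 1 was shallower, with a median of 6076020.5 counts against 17712463 in run 2 and 18315945 in run 3. Culture accounted for 88.4% of the spread along the first principal component, which held 27.3% of the variance, and class for 35.2% along the second, which held 12.9%. Below, log2 fold changes are followed by their standard error (SE), and adjusted p is Benjamini-Hochberg over the 16783 genes tested with edgeR, two-sided.

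LPS raised IL36G, an epithelial and myeloid IL-1 family cytokine (chromosome 2, 112973203 to 112985665), by 5.59 ± 0.76 in healthy donors (adjusted p = 3.09e-06, 7 of 7 donors). The rise was 7.08 ± 0.96 in uncomplicated CVID (adjusted p = 3.51e-06, 5 of 5) and 9.995 ± 0.87 in complicated CVID (adjusted p = 1.12e-10, 9 of 9). The mannose receptor gene MRC1 (chromosome 10, 17809344 to 17911170) fell in all 3 classes, with log2 fold changes of -8.31 ± 0.65, -8.30 ± 0.73 and -7.04 ± 0.52 in the same order. In healthy donors, MRC1 went from a mean of 640.02 to 2.19 CPM (counts scaled to library size). SERPINB4, a serine protease inhibitor, rose by 9.88 ± 1.07, 12.71 ± 1.52 and 12.46 ± 1.05. The chaperone gene CLGN rose by 4.52 ± 0.61, 5.89 ± 0.78 and 7.40 ± 0.64. Over all medium libraries of each class, in the same order, IL36G had 275, 103 and 26 counts and SERPINB4 18, 1 and 9. Sizes of rises from so few counts are uncertain. Neither gene's response differed between classes by edgeR, with or without donor as a block.

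TGFBI, an extracellular matrix protein, changed by -8.17 ± 0.66, -7.67 ± 0.73 and -8.29 ± 0.57, and FPR3, a formyl peptide receptor, by -11.12 ± 0.97, -10.21 ± 0.90 and -9.93 ± 0.68. FPR3 had 1, 5 and 11 counts over the LPS libraries of each class, so that the size of its fall is uncertain. The transporter SLCO2B1 changed by -9.10 ± 0.77, -8.99 ± 0.81 and -9.17 ± 0.65, and GPNMB, a lysosomal glycoprotein, by -8.49 ± 0.83, -9.45 ± 0.99 and -7.99 ± 0.70. Among genes ranked highest in a single class, TM4SF1, a tetraspan membrane protein, rose by 5.28 ± 0.73 in healthy donors and 7.72 ± 1.00 in uncomplicated CVID. The solute carrier SLCO4A1 rose by 3.70 ± 0.30 and the ubiquitin ligase MARCH3 by 2.59 ± 0.22 in complicated CVID, where the nuclear lamina gene LMNA changed by -4.00 ± 0.33 and TXNIP, a thioredoxin inhibitor, by -1.13 ± 0.10. Each of these passed the test, in the stated direction in every donor of the class.

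Of the 20 NF-kB feedback genes, 11 rose in healthy donors, 13 in uncomplicated and 17 in complicated CVID, and none fell. The counts adjusted over the list alone were 15, 15 and 17 raised, with 1 lowered in healthy donors. ZC3H12A, an RNase that degrades cytokine mRNA, rose by 1.21 ± 0.23, 1.46 ± 0.27 and 2.23 ± 0.21, and NFKB2 by 0.88 ± 0.17, 1.09 ± 0.20 and 1.35 ± 0.15. The list's median was 0.76 (camera adjusted p = 2.07e-10), 1.098 (5.49e-11) and 1.498 (6.75e-16), against adjusted p = 0.315, 0.246 and 0.321 with an estimated correlation. Of 18 proinflammatory cytokine genes, 5, 8 and 11 rose, and CSF1 fell in healthy donors. Adjusted over the list alone, 8, 9 and 13 rose, and 1, 0 and 1 fell. IL6 rose by 3.53 ± 0.91, 6.25 ± 1.23 and 7.87 ± 0.99, and CSF3, the granulocyte growth factor, by 5.71 ± 0.88, 9.32 ± 1.29 and 11.81 ± 1.12. CSF3 had 501, 25 and 14 counts over the medium libraries of each class, so that the size of its rise in the patients is uncertain. The cytokine medians were 1.04, 1.80 and 2.35 (camera adjusted p = 8.03e-06, 4.9e-08 and 1.17e-06), against adjusted p = 0.315, 0.223 and 0.321 with an estimated correlation. That of uncomplicated CVID was 0.87 without replicate 1 and 0.96 without replicate 5.

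Monocyte markers went the other way: 9 of 16 fell in each class, and 2 rose in complicated CVID. The counts were 10, 11 and 9 adjusted over the list alone. The scavenger receptor CD36 changed by -6.77 ± 0.78, -7.40 ± 0.90 and -7.80 ± 0.70, and LYZ, lysozyme, by -4.40 ± 0.62, -5.04 ± 0.75 and -4.34 ± 0.55. The medians were -2.26, -2.73 and -1.75 (camera adjusted p = 1.43e-09, 1.35e-09 and 0.000155), and adjusted p = 0.315, 0.223 and 0.433 with an estimated correlation. Inflammatory chemokines split, with 4 raised and 7 lowered of 21 in healthy donors, 7 and 6 in uncomplicated, and 11 and 6 in complicated CVID. They were, adjusted over the list alone, 7 and 7, 9 and 6, and 12 and 6. The monocyte attractant CCL2 changed by -4.75 ± 0.55, -4.26 ± 0.64 and -3.81 ± 0.47, while CCL20, which attracts Th17 cells, rose by 2.79 ± 0.61, 4.39 ± 0.79 and 5.06 ± 0.60. The chemokine median was 1.99 in complicated CVID (camera adjusted p = 0.00288), against adjusted p = 0.76 with an estimated correlation.

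Cholesterol synthesis genes rose in each class, 8, 9 and 9 of 15, or 8, 13 and 10 adjusted over the list alone. SQLE, squalene epoxidase, rose by 0.60 ± 0.18, 1.00 ± 0.21 and 0.94 ± 0.16. The cholesterol medians were 0.30, 0.54 and 0.35 (camera adjusted p = 6.11e-06, 1.82e-10 and 5.8e-05), with adjusted p = 0.315, 0.0665 and 0.321 with an estimated correlation. Class II antigen presentation genes fell, 4, 4 and 9 of 16, or 4, 7 and 9 adjusted over the list alone. HLA-DRA changed by -1.38 ± 0.39, -1.61 ± 0.47 and -2.92 ± 0.37. In complicated CVID the class II median was -1.87 (camera adjusted p = 4.9e-05), and adjusted p = 0.42 with an estimated correlation. Metallothionein genes, which bind zinc, rose for 0, 2 and 6 of 8, with 7 adjusted over the list alone in complicated CVID, where MT1A rose by 4.67 ± 0.93 (adjusted p = 0.000163, 9 of 9 donors). The immediate early genes FOS and EGR2 fell in each class, FOS by -3.02 ± 0.68, -4.34 ± 0.85 and -3.67 ± 0.61.

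In total LPS raised 646 and lowered 1077 genes in healthy donors, 674 and 1039 in uncomplicated CVID, and 1858 and 2337 in complicated CVID. The classes had 7, 5 and 9 donors, and the median SE over genes was 0.255, 0.287 and 0.221. These counts, and those of the lists above, therefore do not compare the breadth of the response. The 3 classes shared 366 raised and 763 lowered genes, where independent calls would share 2.9 and 9.3, and no gene was called in opposite directions. With donor as a block, the counts were 1965 and 2113, 2045 and 2078, and 2984 and 3341, and 24 genes were called in opposite directions. The total of 1723 genes in healthy donors became 1128 without healthy donor 6. That of 1713 in uncomplicated CVID became 929, 878 and 829 without replicates 1, 2 and 5.

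**Figure D1:**
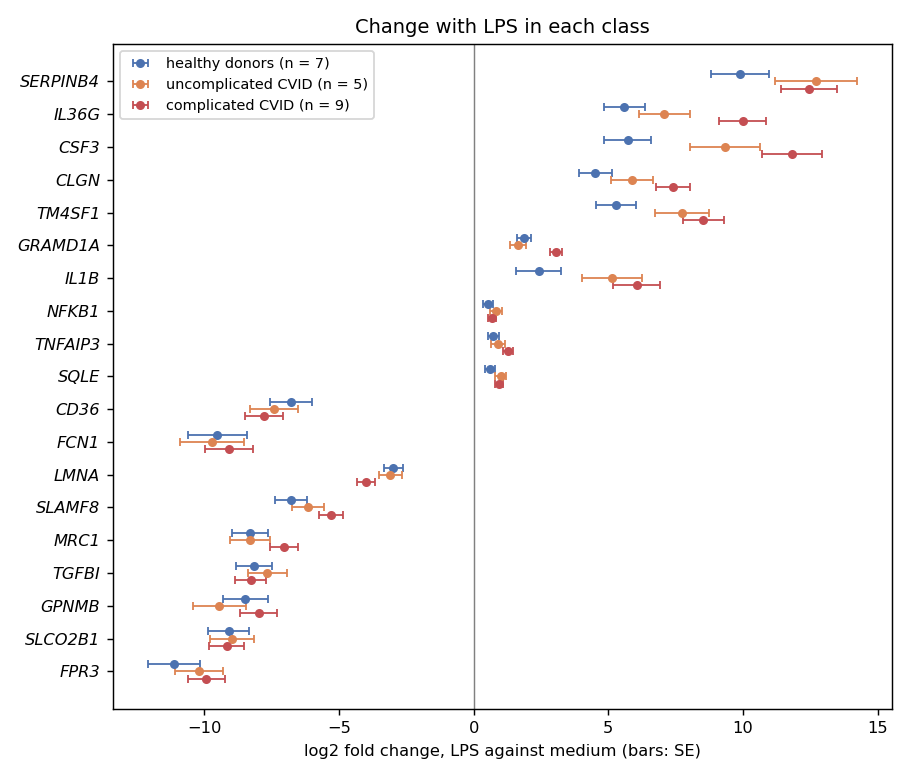
Log2 fold change of 19 genes with LPS against medium (horizontal axis) in healthy donors (n = 7), uncomplicated CVID (n = 5) and complicated CVID (n = 9), with points for the estimates and bars for the SE. IL36G sits at 5.59, 7.08 and 9.995 and MRC1 at -8.31, -8.30 and -7.04 in the 3 classes.

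In medium alone, 218 genes were lower and 119 higher in complicated CVID than in healthy donors. CNR1, the cannabinoid receptor (chromosome 6, 88139864 to 88166359), was lower by a log2 fold change of -3.98 ± 0.65 (adjusted p = 0.00102), and CCL22, a chemokine of dendritic cells (chromosome 16, 57358772 to 57366190), by -3.42 ± 0.56 (adjusted p = 0.00106). CCL22 averaged 28.99 ± 26.73 (SD, n = 9) CPM in complicated CVID and 294.44 ± 98.9 (SD, n = 7) in healthy donors. CCR7, which guides naive lymphocytes to lymph nodes (chromosome 17, 40553769 to 40565472), was lower at -1.23 ± 0.23 (adjusted p = 0.00439). The gene of IgG4 constant region, IGHG4, was lower at -7.50 ± 1.26 (adjusted p = 0.00106), a value that shares uncertainty with its IgG paralogs because such reads are hard to assign. IGHG4 had 2 counts over the medium libraries of complicated CVID, so that the size of its difference is uncertain. Also lower were TEX9 (-2.78 ± 0.43), DDIT4, a stress-induced inhibitor of mTOR (-1.53 ± 0.25), ADTRP (-2.04 ± 0.35), TSPAN13 (-2.55 ± 0.46), ENAM (-4.04 ± 0.76) and FAM177B (-1.89 ± 0.36). All 10 were lower in 9 of 9 patients, counted against the healthy donors' median.

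Genes higher in complicated CVID in medium included NFIA, a transcription factor (chromosome 1, 60865259 to 61462793), at 1.18 ± 0.25 (adjusted p = 0.0104, 8 of 9 patients). MS4A4E reached 3.37 ± 0.77, the selenium carrier SELENOP 3.41 ± 0.79, the cytokine-like CYTL1 3.69 ± 0.84 and the urate transporter SLC2A9 1.48 ± 0.35. CYTL1 had 7 counts over the healthy donors' medium libraries, so that the size of its difference is uncertain. VAMP5, a vesicle fusion protein, was higher by 1.32 ± 0.30, NHS by 2.29 ± 0.51, the glycosyltransferase GCNT1 by 1.32 ± 0.31 and RDH10, a retinol dehydrogenase, by 1.31 ± 0.31. CRTAM, a receptor of activated cytotoxic T cells, was higher by 2.66 ± 0.63 with a wide spread between patients, 102.72 ± 242.46 (SD, n = 9) CPM.

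Of 12 switched memory B cell genes, 5 were lower and none higher, and 7 were lower adjusted over the list alone. Besides IGHG4 these were IGHE (-4.12 ± 0.89), IGHA2 (-5.36 ± 1.16), IGHA1 (-4.88 ± 1.24) and COCH, a marker of long-lived memory B cells (-1.74 ± 0.35), all in 9 of 9 patients. The list's median was -2.65 (camera adjusted p = 7.16e-12), and adjusted p = 0.0268 with an estimated correlation. Of 20 B cell genes, VPREB3 (-3.29 ± 0.73), PAX5, the B lineage regulator (-2.82 ± 0.78), and SPIB (-2.44 ± 0.68) were lower, and 15 adjusted over the list alone. The B cell median was -2.11 (camera adjusted p = 2.3e-16), against adjusted p = 0.191 with an estimated correlation. Of 9 plasma cell genes, MZB1 was lower (-3.11 ± 0.75), or 4 adjusted over the list alone. Immunoglobulin variable segments, taken as a set, had a median of -2.98, with 31 of 99 lower and none higher (p = 0.00321 with an estimated correlation). It was -1.37 with 0 of 64 called by edgeR within run 1 and -6.54 with 19 of 99 within run 3, and with only the 2 groups fitted -2.97 with 0 of 73, while DESeq2 called 64 with all groups. Without a donor the number called was 6 (complicated CVID 6) to 83 (complicated CVID 1), with medians of -2.33 and -5.19.

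The lower B cell values were uneven among the patients. Complicated CVID 2 and 5 had B cell scores of 0.418 and 0.604 (mean log2 CPM over the list), while complicated CVID 1, 8 and 9, at 4.487, 4.603 and 4.993, lay within the healthy donors' range of 3.779 to 5.299. Without complicated CVID 5 the B cell median was -1.58 and without complicated CVID 1 it was -3.20, and the switched memory medians were -1.81 and -4.97. Within run 1 the B cell median was -1.09 and within run 3, which held complicated CVID 5 and 6 alone, -3.85, and the switched memory medians were -0.85 and -5.10. Without the run term the B cell median was -1.10. T cell genes had within-run medians of 0.21 and 0.25.

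**Figure D2:**
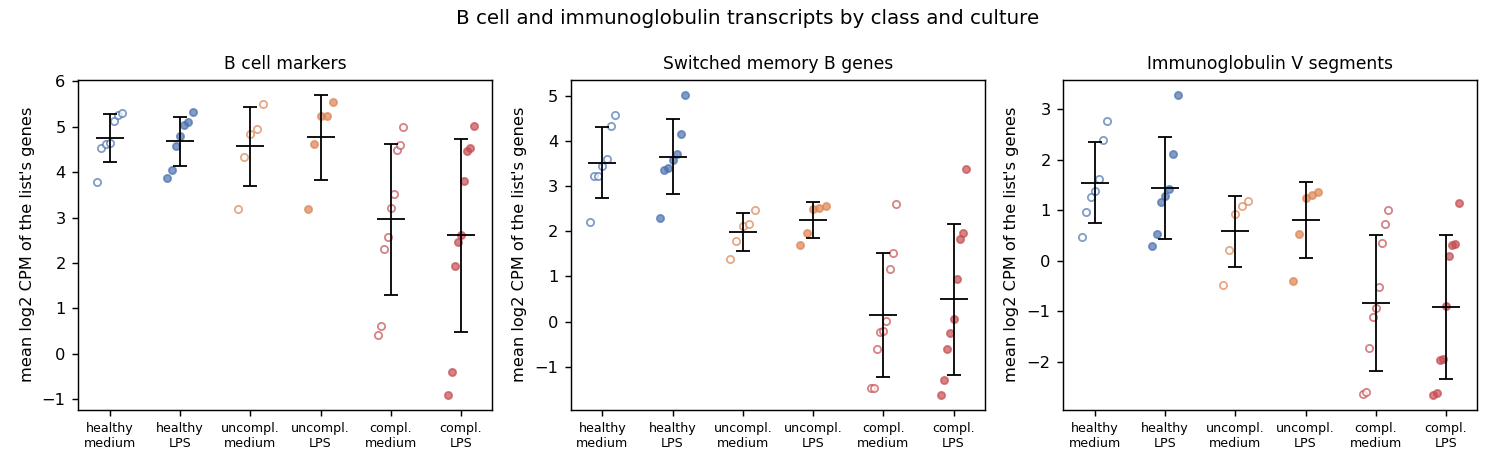
Mean log2 CPM of B cell genes, switched memory B cell genes and immunoglobulin variable segments (vertical axes) in each library (points), by class and culture, with the mean (dash) and SD (bars). Medium and LPS libraries of complicated CVID lie lowest on average, with fitted differences from healthy donors in medium of -2.11, -2.65 and -2.98 (medians over genes).

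Of 18 proinflammatory cytokine genes, CSF3 (-5.84 ± 1.21, 7 of 9 patients), EBI3, a subunit of IL-27 and IL-35 (-2.17 ± 0.50, 9 of 9), IL6 (-4.09 ± 0.97, 8 of 9) and IL36G (-3.58 ± 0.96, 9 of 9) were lower in medium. Adjusted over the list alone, 8 were lower, and the median was -0.68 (camera adjusted p = 0.00573, and adjusted p = 0.537 with an estimated correlation). Within runs 1 and 3 it was -2.33 and -0.66, without complicated CVID 5 -1.78, and without complicated CVID 6 -0.49 (camera adjusted p = 0.124). Healthy donors 1 and 7 had the highest cytokine scores of their group in medium (4.747 and 5.123, mean log2 CPM), and lay at 2 and 6.5 on the first principal component, the others at 44.5 to 63.1. Without healthy donor 7, none of the 4 genes passed with edgeR (CSF3 -4.33, EBI3 -1.84, IL6 -3.15 and IL36G -3.05, adjusted p = 0.0599 to 0.12). Without healthy donor 1, IL6 (-3.37) and IL36G (-3.23) did not pass, and without complicated CVID 6, EBI3 (-1.95), IL6 (-3.95) and IL36G (-3.83) did not. The call of IL36G also ended without any of healthy donors 2 and 3 and complicated CVID 1, 2, 3, 5, 8 and 9 (log2 fold changes of -3.22 to -3.95). Of 21 chemokines CCL22 alone was lower, over all genes and adjusted over the list alone, with a median of -1.101 (camera adjusted p = 6.07e-07, and adjusted p = 0.484 with an estimated correlation) and within-run medians of -1.65 and -1.14. RELB was lower among 20 NF-kB feedback genes (-0.67 ± 0.18, 3 adjusted over the list alone). That median was -0.44 (camera adjusted p = 0.00155, and adjusted p = 0.629 with an estimated correlation), -0.61 within run 1, 0.09 within run 3, -0.28 without healthy donor 7 and -0.68 without complicated CVID 5.

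Dendritic cell genes went both ways: FCER1A (3.34 ± 0.84) and CLEC10A (2.95 ± 0.75) of conventional dendritic cells were higher. Adjusted over the list alone, 4 of 10 were higher and 4 lower, the plasmacytoid markers CLEC4C (-3.27 ± 1.1, adjusted p = 0.103) and LILRA4 (-2.36 ± 0.81, adjusted p = 0.109) among the latter. TIGIT, an inhibitory receptor of T and NK cells, was higher (1.21 ± 0.31, 9 of 9) among 15 genes of Th1 and T cell activation, 3 adjusted over the list alone, with a median of 0.76 (camera adjusted p = 0.00573, and adjusted p = 0.537 with an estimated correlation), or 0.42 without complicated CVID 5 (camera adjusted p = 0.423). Cholesterol synthesis genes SQLE (-0.77 ± 0.18) and SREBF2, their transcriptional activator (-0.37 ± 0.10), were lower, as were 4 of 15 adjusted over the list alone (median -0.23, camera adjusted p = 0.00135, and adjusted p = 0.484 with an estimated correlation). The median of naive T genes was -0.53 and that of cytotoxic and NK genes 0.61 (camera adjusted p = 0.00135 for each, and adjusted p = 0.537 with an estimated correlation), the latter 0.27 without complicated CVID 1.

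In total 337 genes differed between complicated CVID and healthy donors in medium, 119 higher and 218 lower. Fitting only these 2 groups gave 0 genes (2890 had an unadjusted p under 0.05 with all groups fitted, and DESeq2 called 875), within run 1 there were 0 and within run 3 251. The count became 179, 152 and 156 without healthy donors 1, 6 and 7, and 708, 541 and 65 without complicated CVID 1, 4 and 6. Of the 10 lower genes named first, none lost its call when any donor was left out.

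Uncomplicated CVID and healthy donors shared no run, so that their difference in medium rested on the run term carried by complicated CVID. No gene passed the test with edgeR, the smallest adjusted p being 0.117, while 1413 had an unadjusted p under 0.05, DESeq2 called 84 and limma voom 0. Adjusted over the list alone, 8 of 21 chemokines were lower, including CXCL3 (-3.46 ± 0.88, adjusted p = 0.213) and CXCL2 (-3.07 ± 0.79, adjusted p = 0.215), both neutrophil attractants and lower in 5 of 5 patients. That list's median was -1.503 (camera adjusted p = 2.93e-12), against adjusted p = 0.299 with an estimated correlation. Of 18 cytokines 5 were lower adjusted over the list alone, with IL1A at -4.05 ± 1.11 and OSM at -2.83 ± 0.80 (adjusted p = 0.232 and 0.243, 5 of 5 patients). Their median was -1.19 (camera adjusted p = 0.000286, and adjusted p = 0.51 with an estimated correlation). Of 14 T cell genes 6 were higher adjusted over the list alone, CD3E at 0.90 ± 0.25 (adjusted p = 0.237, 2 of 5 patients). The T cell median was 0.48 (camera adjusted p = 5.03e-05, and adjusted p = 0.51 with an estimated correlation), 0.22 without uncomplicated CVID 4 and 0.14 without the run term (camera adjusted p = 0.514). The B cell median was -1.25 (camera adjusted p = 8.16e-13, and adjusted p = 0.33 with an estimated correlation) and became -0.04 without the run term (camera adjusted p = 0.314). Switched memory B genes had a median of -0.96 (camera adjusted p = 1.12e-05, and adjusted p = 0.299 with an estimated correlation, none of 12 called over all genes or over the list alone), which was -1.18 without the run term (camera adjusted p = 5.42e-08). It was -1.81, -2.24 and -2.01 without healthy donors 1, 2 and 3, and -0.76 to -1.23 without any other donor.

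Between complicated and uncomplicated CVID in medium no gene passed the test with edgeR either, the smallest adjusted p being 0.14, while 1381 had an unadjusted p under 0.05, DESeq2 called 6 and limma voom 0. CLEC4C, a plasmacytoid dendritic cell lectin, was at -3.52 ± 1.01 (adjusted p = 0.495, lower in 9 of 9) and was the 1 dendritic cell gene of 10 lower adjusted over the list alone. FOXP3, the Treg regulator, was at -1.26 ± 0.43 (adjusted p = 0.536) and also passed adjusted over the list alone. Switched memory B genes had a median of -1.36, T cell genes of -0.38 and monocyte genes of 0.72 (each camera adjusted p = 0.00141, and adjusted p = 0.677 with an estimated correlation). Within run 2, which holds 4 complicated and all 5 uncomplicated patients, these medians were -1.85, -0.37 and 0.64. Uncomplicated CVID 4 carried much of the T cell and monocyte differences, with the highest T cell score (8.397) and the lowest monocyte score (3.471) of its group in medium. Without this donor the medians were -0.14 and 0.44 (camera adjusted p = 0.235 and 0.275). The monocyte median was 0.22 without complicated CVID 7, and the T cell median -0.12 without the run term (camera adjusted p = 0.177).

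With LPS, complicated CVID again showed lower B cell and immunoglobulin genes than healthy donors. IGHG4 was lower by -5.81 ± 1.26 and IGHE by -4.22 ± 0.92 (adjusted p = 0.015 for each, 9 of 9 patients). IGHG4 had 6 counts over these patients' LPS libraries, so that the size of its difference is uncertain. Of 12 switched memory B genes 6 were lower adjusted over the list alone. The list's median was -2.44 (camera adjusted p = 1.13e-10), and adjusted p = 0.0473 with an estimated correlation, or -4.82 without complicated CVID 1. VPREB3 (-3.40 ± 0.79, 7 of 9), BACH2, a repressor of plasma cell differentiation (-1.15 ± 0.31, 9 of 9), and PAX5 (-2.92 ± 0.79, 9 of 9) were the lower ones of 20 B cell genes, and 17 were lower adjusted over the list alone. The B cell median was -2.05 (camera adjusted p = 1.31e-18), against adjusted p = 0.164 with an estimated correlation, -0.99 and -4.02 within runs 1 and 3, and -1.19 without the run term. Immunoglobulin variable segments had a median of -3.20, with 33 of 99 lower (p = 0.00502 with an estimated correlation). It was -1.29 within run 1 and -7.22 within run 3, and the number called fell to 1 of 68 with only the 2 groups fitted and ranged from 2 (complicated CVID 6) to 78 (complicated CVID 1) with a donor left out.

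Other genes lower with LPS in complicated CVID were MCM2, of the replicative helicase (chromosome 3, 127598223 to 127622436), at -1.08 ± 0.22 (adjusted p = 0.0114), and VARS, valyl-tRNA synthetase (chromosome 6, 31777518 to 31795953), at -1.02 ± 0.22 (adjusted p = 0.0141). TRAF4, an adaptor of TNF receptor family signalling, was at -1.29 ± 0.26 (adjusted p = 0.0099), the matrix growth factor CTGF at -4.51 ± 0.81 and PARM1 at -3.32 ± 0.58. ALPL, alkaline phosphatase, was at -3.73 ± 0.78, MARK1 at -3.84 ± 0.82, LARGE2 at -2.67 ± 0.57, ENAM at -4.80 ± 0.84 and TEX9 at -2.46 ± 0.45. Each was lower in 9 of 9 patients. MARK1 had 4 and ENAM 9 counts over the LPS libraries of complicated CVID, each in 3 of 9 libraries. The sizes of these 2 differences are uncertain. The mitochondrial chaperonin HSPD1 was lower at -0.71 ± 0.13 (adjusted p = 0.00581).

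Higher with LPS were ST8SIA1, a ganglioside sialyltransferase (chromosome 12, 22063773 to 22437041), at 1.28 ± 0.24 (adjusted p = 0.00763, 8 of 9), the repressor TRPS1 at 1.02 ± 0.21 and TRGC2, a T cell receptor gamma constant gene, at 1.33 ± 0.31. CDA, cytidine deaminase, reached 2.77 ± 0.62, ATP10B 1.92 ± 0.40, RDH10 1.504 ± 0.33, PRG4, lubricin, 2.00 ± 0.48, and DAPK2 1.18 ± 0.28. KIAA1671 was higher by 1.09 ± 0.24 and CYTL1 by 4.29 ± 1.05. CYTL1 had few counts in any library, 49 over 6 of 9 complicated and 2 in 1 of 7 healthy LPS libraries. The size of its difference is therefore uncertain. TIGIT stayed higher (1.25 ± 0.31, adjusted p = 0.0301, 9 of 9), 1 of 15 genes of Th1 and T cell activation and 3 adjusted over the list alone (median 0.57, camera adjusted p = 0.00417, and adjusted p = 0.594 with an estimated correlation, or median 0.40 and camera adjusted p = 0.0542 without complicated CVID 5).

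No inflammasome gene passed over all genes, and 6 of 13 were higher and 1 lower adjusted over the list alone, among them CASP4 (0.75 ± 0.24, adjusted p = 0.0843) and NLRP3 (1.12 ± 0.41, adjusted p = 0.121). The median was 0.74 (camera adjusted p = 0.0147, and adjusted p = 0.594 with an estimated correlation), 0.48 without complicated CVID 2 and 0.62 without complicated CVID 6 (camera adjusted p = 0.0595). Cytotoxic and NK genes had a median of 0.84 (camera adjusted p = 8.38e-05, and adjusted p = 0.594 with an estimated correlation). Class II genes had a median of -0.55 (camera adjusted p = 0.00417, HLA-DOB lower by -1.35 ± 0.31), against adjusted p = 0.621 with an estimated correlation, and of -0.35 without complicated CVID 6.

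In total 337 genes differed with LPS between complicated CVID and healthy donors, 107 higher and 230 lower. Fitting only the 2 groups gave 46 genes, leaving out the 4 shallowest libraries 121, run 1 alone 0 and run 3 alone 403. Without healthy donors 1, 3, 5, 6 and 7 there were 152, 218, 160, 151 and 193, and without complicated CVID 1, 2, 4, 6 and 8 there were 926, 159, 681, 15 and 218.

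Against healthy donors, uncomplicated CVID with LPS showed 12 genes past the test, 8 higher and 4 lower. FKBP5, a glucocorticoid-induced co-chaperone (chromosome 6, 35573585 to 35728583), was higher by 1.04 ± 0.20 and the metalloprotease ADAM12 lower by -2.94 ± 0.53 (adjusted p = 0.0414 for each, 5 of 5 patients). KLRG1, an inhibitory receptor of NK and effector T cells, was higher by 2.13 ± 0.45, NCK1 by 0.77 ± 0.16, TFIP11 by 0.55 ± 0.11, DAXX by 0.57 ± 0.11 and SOAT2, near the detection floor in healthy donors, by 8.40 ± 1.75. PDE8A, a cyclic AMP phosphodiesterase, was at -1.05 ± 0.22, DNAH17 at -1.92 ± 0.39 and ATAD5 at -0.98 ± 0.20. Of 14 T cell genes 7 were higher adjusted over the list alone, with a median of 0.72 (camera adjusted p = 1.38e-06), or 0.31 without the run term. Of 17 cytotoxic and NK genes 6 were higher adjusted over the list alone, with a median of 1.21 (1.8e-06), or 0.75 without the run term, NKG7 at 2.01 ± 0.66 (adjusted p = 0.197, 4 of 5 patients). With an estimated correlation both lists had an adjusted p = 0.566. B cell genes had a median of -1.07 (camera adjusted p = 3.72e-09, and adjusted p = 0.566 with an estimated correlation), which was 0.16 without the run term (camera adjusted p = 0.841). Switched memory B genes had a median of -1.54 (camera adjusted p = 8.81e-05, and adjusted p = 0.566 with an estimated correlation, none of 12 called over all genes or over the list alone), -1.67 without the run term and -1.29 to -2.16 with a donor left out. Chemokine, NF-kB feedback and monocyte lists were also lower. Without the run term their medians were -0.65, -0.39 and -0.40 (camera adjusted p = 0.00169, 0.000429 and 0.0189). None of the 3 passed without uncomplicated CVID 4 (-0.76, -0.05 and -0.19) or with an estimated correlation. The count of 12 became 7, 0, 0, 0, 40, 3 and 0 without healthy donors 1 to 7 in turn, and 21, 0, 5, 40 and 7 without uncomplicated CVID 1 to 5. It was 0 with only the 2 groups fitted and 0 without the 4 shallow libraries.

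Complicated and uncomplicated CVID differed with LPS in 1568 genes when all groups were fitted, in 0 with only these 2 groups and in 287 without uncomplicated CVID 3. ABCG1, a cholesterol exporter (chromosome 21, 42199689 to 42297244), was higher by 2.29 ± 0.38 (adjusted p = 0.00138, 9 of 9 patients). VEGFA, the vascular growth factor (chromosome 6, 43770184 to 43786487), was higher by 3.19 ± 0.64 (adjusted p = 0.00271), at 129.81 ± 100.14 (SD, n = 9) against 19.13 ± 10.78 (SD, n = 5) CPM. NHP2, of small nucleolar ribonucleoproteins (chromosome 5, 178149460 to 178153967), was lower by -1.19 ± 0.18 (adjusted p = 0.00101), with 18.75 ± 5.52 against 41.64 ± 9.43 CPM. The integrin gene ITGAV was higher by 2.19 ± 0.44, SRGAP1 by 2.18 ± 0.43, the semaphorin SEMA3F by 3.40 ± 0.66, AGPAT4 by 1.79 ± 0.35, SNX21 by 1.30 ± 0.26, TTC28 by 1.94 ± 0.39, TBC1D7 by 1.05 ± 0.22 and DNAH17 by 1.77 ± 0.32. Lower were spermidine synthase SRM (-1.21 ± 0.22), the ribosome assembly factor MRTO4 (-1.18 ± 0.22), GPATCH4 (-1.13 ± 0.21), FARSB, of phenylalanyl-tRNA synthetase (-1.06 ± 0.20), the purine enzyme PAICS (-1.22 ± 0.24), the mitochondrial helicase TWNK, the serine enzyme PSAT1 (-2.58 ± 0.50), MRPL4 (-1.80 ± 0.34) and CCDC85B (-1.79 ± 0.34). The comparison of uncomplicated CVID with healthy donors above uses the same 5 LPS libraries, so that DNAH17, lower there and higher here, is not a separate finding.

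Of 21 inflammatory chemokines 6 were higher and none lower, and 10 were higher and 1 lower adjusted over the list alone. CXCL16 (2.43 ± 0.63), CXCL3 (2.93 ± 0.77), CCL23 (3.19 ± 0.86), CCL18 (2.90 ± 0.78), CXCL2 (2.51 ± 0.68) and CXCL5 (4.05 ± 1.20) were higher in 9 of 9 patients. The list's median was 1.83 (camera adjusted p = 0.000347), against adjusted p = 0.732 with an estimated correlation, and 1.45 within run 2. Of 16 monocyte markers VCAN (3.25 ± 0.89) and CD14 (2.66 ± 0.76) were higher, 6 adjusted over the list alone, with a median of 1.37 (camera adjusted p = 0.000347) and 1.30 within run 2. Of 13 anti-inflammatory cytokines and receptors 4 were higher, also adjusted over the list alone, among them IL24 (2.17 ± 0.58) and IL19 (2.03 ± 0.58), with a median of 0.81 (camera adjusted p = 0.00113). NF-kB feedback genes had a median of 0.68 (camera adjusted p = 0.000332), or 0.41 without the 4 shallow libraries, with IRAK3, a brake on TLR signalling, higher by 2.16 ± 0.55 and IRAK2 by 1.15 ± 0.37. With an estimated correlation each of these lists had an adjusted p = 0.732.

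The inflammasome sensors NLRP3 (1.62 ± 0.46, adjusted p = 0.0239, 8 of 9) and NLRC4 (2.09 ± 0.60, adjusted p = 0.0243, 9 of 9) were higher, and GSDMD, the pore protein, was lower (-0.72 ± 0.18), so that this list of 13 went both ways. Of 15 cholesterol synthesis genes 5 were lower, among them FDFT1 (-0.82 ± 0.15) and MSMO1 (-0.82 ± 0.20), and LSS was higher (0.73 ± 0.22). Adjusted over the list alone 9 were lower, with a median of -0.45 (camera adjusted p = 0.00108, and adjusted p = 0.732 with an estimated correlation). The replication genes PCNA (-0.67 ± 0.13) and MCM2 (-1.05 ± 0.23) and HSPD1 (-0.79 ± 0.14) were lower, PCNA in 8 and the others in 9 of 9. TRAC, the T cell receptor alpha constant gene, was lower (-0.90 ± 0.28). B cell genes had a median of -0.93 (camera adjusted p = 0.0074, or -0.63 and 0.302 without complicated CVID 3) and platelet genes of 1.21 (camera adjusted p = 0.0291), both with adjusted p = 0.732 with an estimated correlation. The platelet call ended without the run term (1.37) and without uncomplicated CVID 1 (1.05) or complicated CVID 3 or 8 (0.98 and 1.08), and without complicated CVID 2 (camera adjusted p = 0.0599). CD1C, of conventional dendritic cells, was lower by -3.25 ± 0.73.

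Of the 1568 genes that differed between complicated and uncomplicated CVID with LPS, 630 were higher and 938 lower, and RLE scaling changed the split to 755 higher and 659 lower. Within run 2 there were 443, without the 4 shallow libraries 937, with limma voom 969 and with only the 2 groups fitted 0 with edgeR, while 4218 genes had an unadjusted p under 0.05 and DESeq2 called 2283. The count became 900 and 287 without uncomplicated CVID 2 and 3, and 1010, 724 and 906 without complicated CVID 3, 7 and 8. The 20 genes named first kept their calls with any donor left out.

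**Figure D3:**
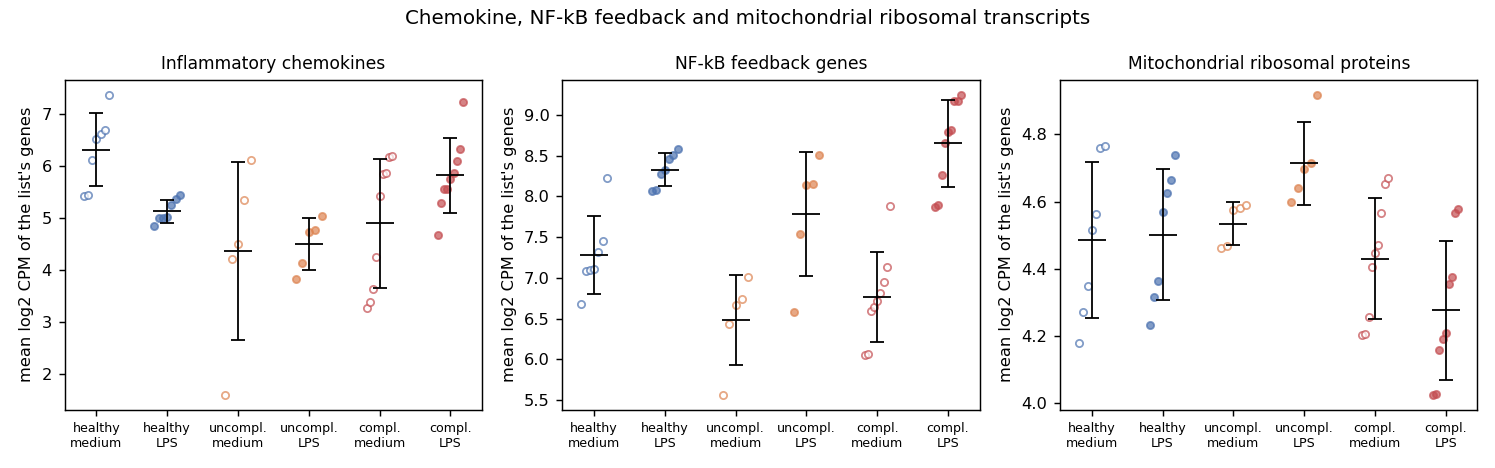
Mean log2 CPM of inflammatory chemokines, NF-kB feedback genes and mitochondrial ribosomal protein genes (vertical axes) per library (points), by class and culture, with mean (dash) and SD (bars). With LPS, the fitted median difference of complicated from uncomplicated CVID was 1.83 for chemokines, 0.68 for NF-kB feedback genes and -0.48 for mitochondrial ribosomal genes.

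The response to LPS was then compared between classes as a difference of differences. Chemokine genes responded more in complicated CVID than in healthy donors, with a median difference of 2.27 and 9 of 21 higher adjusted over the list alone (camera adjusted p = 1.02e-15, and adjusted p = 0.233 with an estimated correlation). This median was 2.93 within run 1 and 1.28 within run 3, and the chemokine medians behind it were -1.101 in medium and 0.74 with LPS. The mean log2 CPM of these genes fell with LPS in 7 of 7 healthy donors (mean change -1.18) and rose in 5 of 9 complicated (0.92) and 3 of 5 uncomplicated patients (0.15). Monocyte markers did not pass, with a median response difference of 0.51 from healthy donors (none of 16 called over all genes or over the list alone, camera adjusted p = 0.0903, and adjusted p = 0.924 with an estimated correlation), 0.51 within run 1 and 1.22 within run 3. NF-kB feedback genes (median 0.74, 4 of 20 adjusted over the list alone, camera adjusted p = 7.09e-12) and proinflammatory cytokines (1.48, 9 of 18 adjusted over the list alone, 3.08e-07) also had higher medians, both with adjusted p = 0.284 with an estimated correlation. Within runs 1 and 3 the NF-kB medians were 0.81 and 0.33 and the cytokine medians 3.17 and 0.48. The mean cytokine score (log2 CPM) was 2.49 in complicated CVID and 3.89 in healthy donors in medium, and 5.88 and 5.61 with LPS. The NF-kB score was 6.76 and 7.28 in medium, and 8.65 and 8.33 with LPS. Lower values in medium thus made up much of the cytokine response difference. Class II genes responded more negatively (-0.90, 2 of 16 adjusted over the list alone, camera adjusted p = 0.000101, and adjusted p = 0.729 with an estimated correlation), by -0.52 without complicated CVID 5. Uncomplicated CVID differed from healthy donors in chemokines by 1.07 (1.93e-08) and in cytokines by 1.38 (5.16e-07), the camera adjusted p in brackets, and adjusted p = 0.507 for both with an estimated correlation. Its mean scores (log2 CPM, no run term) with LPS were below those of healthy donors, chemokines 4.5 against 5.13 and cytokines 5.03 against 5.61. In medium they were 4.35 against 6.31 and 2.13 against 3.89. By these means the differences of response lay in lower values in medium, not in higher ones with LPS. The 2 classes shared no run, so that class and run cannot be told apart in the level of either culture. Which culture the differences came from is therefore not settled. The chemokine response difference was 0.67 without healthy donor 7 and 1.86 without uncomplicated CVID 3, and the cytokine one 2.10 without the latter. Complicated differed from uncomplicated CVID in class II genes by -0.77 (camera adjusted p = 0.000611) and in NF-kB feedback genes by 0.38 (0.000933), both with adjusted p = 0.936 with an estimated correlation. The class II value was -0.49 without complicated CVID 5, and the NF-kB value 0.23 without the 4 shallow libraries, 0.25 without uncomplicated CVID 4 and 0.63 without complicated CVID 5. Chemokine, interferon-stimulated and interferon-gamma-induced genes also differed, by 0.68, -0.85 and -0.89 without the run term (camera adjusted p = 0.013 for each). The chemokine value was 0.01 without uncomplicated CVID 3 (camera adjusted p = 0.708). Chemokines also did not pass without uncomplicated CVID 5 or complicated CVID 2, 6 or 9 (camera adjusted p = 0.207, 0.0529, 0.354 and 0.19). The same held without the 4 shallow libraries (camera adjusted p = 0.0769). Neither interferon list passed without uncomplicated CVID 2 (camera adjusted p = 0.292 and 0.152) or without uncomplicated CVID 1 (0.0581 and 0.108). Interferon-stimulated genes also did not pass without complicated CVID 2 (camera adjusted p = 0.111).

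No single gene passed the test of a different response with edgeR: 1071, 151 and 1068 genes had an unadjusted p under 0.05 for complicated CVID against healthy donors, uncomplicated CVID against healthy donors, and complicated against uncomplicated CVID. DESeq2 called 64, 0 and 0 and limma voom 2, 0 and 3. With donor as a block edgeR called 5, 0 and 12. SRGAP1 was raised more in complicated CVID than in healthy donors, by 1.93 ± 0.27 (adjusted p = 0.005), and than in uncomplicated CVID by 1.84 ± 0.29 (adjusted p = 0.0115), rising in 9 of 9, 7 of 7 and 5 of 5 donors. NLRP3 rose with LPS in 9 of 9 complicated, 5 of 7 healthy and 1 of 5 uncomplicated donors, and its response differed by 0.83 ± 0.14 (adjusted p = 0.0271) and 1.23 ± 0.16 (adjusted p = 0.00096). In fits without the block, the NLRP3 difference from healthy donors was 0.81 within run 1 and 0.88 within run 3. That from uncomplicated CVID was 1.26 within run 2, also without the block. Over all runs NLRP3 did not pass with edgeR without the block (adjusted p = 0.901 and 0.78). MMP2, a matrix metalloprotease, differed by 2.67 ± 0.43 between the patient classes (adjusted p = 0.023).

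**Figure D4:**
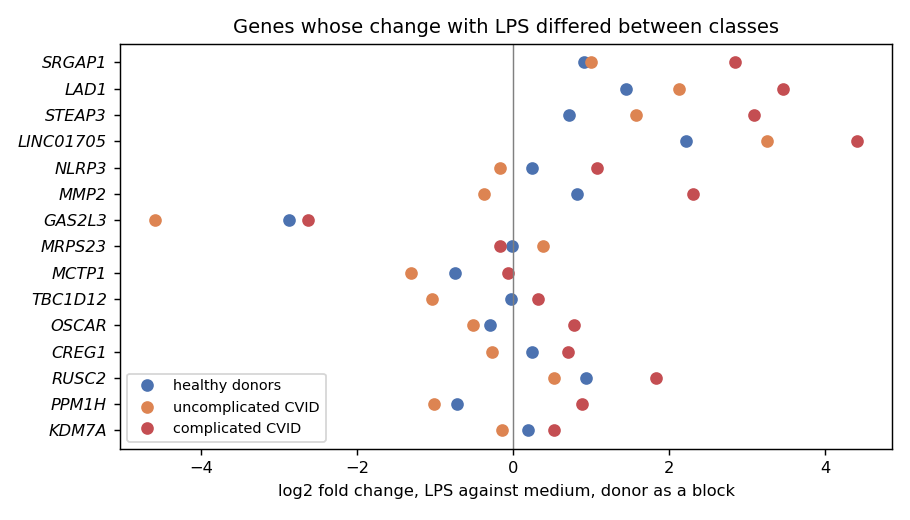
Log2 fold change with LPS against medium (horizontal axis), donor as a block, in healthy donors, uncomplicated and complicated CVID (points) for the genes whose response differed between classes in that fit. NLRP3 sits at 0.24, -0.17 and 1.07 and SRGAP1 at 0.91, 1.00 and 2.84 in these classes.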

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

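The comparisons of the response with donor as a block were planned, and the search for samples that stood apart was fixed as a rule. It covered 84 tests of a measure within a group, of which 4 passed, where chance gives about 1 in 20. In the LPS cultures of complicated CVID, replicate 7 had 13696 genes with counts, the next library 19128, and is 1 of the 4 shallowest libraries. In the LPS cultures of uncomplicated CVID, replicate 4 had 19.1% of its counts in its 50 most abundant genes (95% Wilson interval 19.08 to 19.11, which covers counting error only), the next library 15.7%. The same library lay at -24.1 on the first principal component, the nearest of its group at -48.1. In the medium cultures of uncomplicated CVID, replicate 4 lay at -79.7 on the second component, the nearest at -17.6. Leaving out this donor changed the 1568 genes of complicated against uncomplicated CVID with LPS by less than 1.5 times, and the 12 of uncomplicated CVID against healthy donors with LPS to 40.

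With donor as a block, 5 genes responded to LPS more in complicated CVID than in healthy donors: SRGAP1 (1.93 ± 0.27), the epithelial anchoring protein LAD1 (2.01 ± 0.32), the iron reductase STEAP3 (2.37 ± 0.39), the non-coding LINC01705 (2.19 ± 0.38) and NLRP3 (0.83 ± 0.14). Their adjusted p was 0.005 for SRGAP1 and 0.0271 for the others. Between complicated and uncomplicated CVID 12 genes differed. NLRP3 (1.23 ± 0.16), SRGAP1 (1.84 ± 0.29), the metalloprotease MMP2 (2.67 ± 0.43), GAS2L3 (1.95 ± 0.34), MCTP1 (1.25 ± 0.23), TBC1D12 (1.36 ± 0.26), the osteoclast-associated receptor OSCAR (1.30 ± 0.24), CREG1 (0.97 ± 0.19), RUSC2 (1.30 ± 0.25), PPM1H (1.89 ± 0.37) and the histone demethylase KDM7A (0.67 ± 0.13) had the higher log2 fold change with LPS in complicated CVID. For GAS2L3 (-2.63 against -4.59) and MCTP1 (-0.07 against -1.31) this was a smaller fall. The mitochondrial ribosomal gene MRPS23 (-0.55 ± 0.10) had the lower one, -0.17 against 0.38. Their adjusted p ranged from 0.00096 for NLRP3 to 0.0483. Without the block none of these passed, with adjusted p of 0.195 to 0.901, so that the calls rest on pairing the 2 cultures of a donor.

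SRGAP1 rose with LPS in every donor of each class, while NLRP3 rose in 9 of 9 complicated, 5 of 7 healthy and 1 of 5 uncomplicated donors. Without the 4 shallowest libraries the NLRP3 differences were 0.65 and 0.88, in a fit without the block. These 2 values thus differ from those above in both the libraries and the fit. Lists of genes that differed in their response are not counted here, since none held with an estimated correlation.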

How the results depend on the processing

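Leaving out the 4 shallowest libraries was the 1 alternative chosen after the result was seen. Complicated CVID against healthy donors in medium gave 337 genes, 182 without the low-count filter, 188 without the run term, 0 with only the groups compared, 0 within run 1 and 875 with DESeq2. With LPS its 337 genes became 175 without the filter, 221 without the run term, 121 without the 4 shallowest libraries, 46 with only the groups compared, 0 within run 1 and 943 with DESeq2. Leaving out a donor gave 65 (complicated CVID 6) to 708 (complicated CVID 1) genes in medium, and 15 and 926 with LPS for the same 2 donors.

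Complicated against uncomplicated CVID with LPS gave 1568 genes, 903 without the filter, 937 without the 4 shallowest libraries, 0 with only the groups compared, 443 within run 2 and 969 with limma voom. Leaving out a donor gave 287 (uncomplicated CVID 3) to 1726 genes. In medium, where edgeR called 0 (1381 at an unadjusted p under 0.05), DESeq2 called 6, and leaving out a donor gave 0 or 1. Uncomplicated CVID against healthy donors in medium also had 0 calls with edgeR (1413 at an unadjusted p under 0.05), 1 without the run term, 1 with only the groups compared and 84 with DESeq2. With LPS its 12 genes became 7 with RLE, 1 without the filter, 1 without the run term, 0 without the 4 shallowest libraries (edgeR, 2009 genes at an unadjusted p under 0.05 with all libraries), 0 with only the groups compared, 169 with DESeq2 and 1 with limma voom, and 0 to 40 with a donor left out.

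For LPS against medium the donor as a block raised the counts from 1723, 1713 and 4195 to 4078, 4123 and 6325 in healthy donors, uncomplicated and complicated CVID. Limma voom gave 3304 and 3807 in the first 2, and only the groups compared 728 in uncomplicated CVID. Leaving out a donor gave 1128 to 1646, 829 to 2029 and 3588 to 4123. The difference of response between complicated CVID and healthy donors was called for 0 genes with edgeR (1071 at an unadjusted p under 0.05), 5 with the donor block, 12 within run 3, 64 with DESeq2, 2 with limma voom and 0 or 1 with a donor left out. Between the patient classes it was called for 12 with the donor block and 3 with limma voom.

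The replicate number as a block between classes, which pairs different people, gave 729 genes for complicated CVID against healthy donors with LPS, 923 and 9 for complicated against uncomplicated CVID with LPS and in medium, and 0 for uncomplicated CVID against healthy donors with LPS. Blocking ended or made no other call of a count. It turned the median of interferon-gamma-induced genes between the patient classes in medium to -0.113 (adjusted p = 0.522). In the main fit that list had passed as higher in complicated CVID. Its median was 0.76 without the run term (camera adjusted p = 0.000228) and 0.15 without uncomplicated CVID 4 (camera adjusted p = 0.758).

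Of 372 list tests 128 passed with the preset correlation, 2 with an estimated correlation and 116 to 135 with a donor left out. NF-kB feedback genes in uncomplicated CVID against healthy donors with LPS had a median of -0.154 without the filter (adjusted p = 0.68), with the test then pointing up. Among 481 results for named genes no call changed direction in any alternative, and changes of direction in genes called in neither fit were not counted. Of these results 468 kept their outcome with RLE, 427 without the run term, 302 of 448 with only the groups compared, 3 of 65 within run 1, 28 of 60 within run 2, 35 of 74 within run 3, and 3964 of 4606 values with a donor left out.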

Other observations

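The families described in this part, the tests of the chemokine level in the healthy donors' medium cultures and of B cell and platelet scores, and the splits within runs were chosen after the result was seen. The p values of the families were not adjusted for their number. Of 65 mitochondrial ribosomal protein genes 37 were lower and none higher in complicated than in uncomplicated CVID with LPS, with a median of -0.48 (p = 0.00105 by limma's camera with an estimated correlation), and the median was -0.43 with RLE, with 28 lower. Of 10 chaperonin genes, which fold actin, tubulin and mitochondrial proteins, 8 were lower, with a median of -0.51 (p = 0.0074 by limma's camera with an estimated correlation; RLE -0.45). Of 49 genes of complex I and ATP synthase 15 were lower (median -0.31, p = 0.0282 by limma's camera with an estimated correlation; RLE -0.26, 9 lower). Cytosolic ribosomal protein genes had a median of -0.65, with 33 of 74 lower (p = 0.0755 by limma's camera with an estimated correlation; RLE -0.60, 21 lower). Proteasome genes had a median of -0.14 with 2 of 38 lower (p = 0.491 by limma's camera with an estimated correlation).

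The medians of these families moved less than the numbers of genes called. Within run 2 the medians of mitochondrial ribosomal, chaperonin, complex I and ATP synthase, and cytosolic ribosomal genes were -0.43, -0.49, -0.31 and -0.61, with 18, 5, 3 and 1 lower. Without the 4 shallowest libraries they were -0.47, -0.49, -0.31 and -0.57, with 38, 8, 10 and 7 lower. Without uncomplicated CVID 3 they were -0.41, -0.42, -0.26 and -0.62, with 17, 4, 2 and 4 lower. With only the groups compared they were -0.46, -0.51, -0.34 and -0.62, and edgeR called 0 genes of each family (DESeq2 with all groups called 40, 8, 13 and 37). Cytosolic ribosomal genes lower were 6 without complicated CVID 7, 14 without complicated CVID 3 or 5, 20 without complicated CVID 6 or 8, and 13 and 11 without uncomplicated CVID 2 and 4, but 55 without uncomplicated CVID 1 or 5. Complex I and ATP synthase genes lower were 6, 7, 8 and 10 without complicated CVID 3, 7, 8 and 5, and 7 without uncomplicated CVID 2.

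Against healthy donors with LPS, mitochondrial ribosomal genes had a median of 0.30 in uncomplicated CVID, 0.19 without the run term and 0.10 with only the groups compared. The 2 classes shared no run, so this value rests on the run term. In complicated CVID, which shared 2 runs with healthy donors, the median was -0.19 with 5 of 65 lower (p = 0.0627 by limma's camera with an estimated correlation), -0.15 within run 1 and -0.29 within run 3, with none called by edgeR within either run. It was -0.11 without complicated CVID 6 and -0.12 without healthy donor 5. The score was -0.21 ± 0.07 against healthy donors, -0.14 ± 0.09 within run 1 and -0.30 ± 0.15 within run 3. The response to LPS also differed between the patient classes in these genes, with a median of -0.33 for mitochondrial ribosomal genes (p = 0.00267 by limma's camera with an estimated correlation) and -0.38 for chaperonin genes (p = 0.00744 by limma's camera with an estimated correlation). Without a donor block edgeR called no gene (1068 genes at an unadjusted p under 0.05). With donor as a block it called the mitochondrial ribosomal gene MRPS23 (-0.55 ± 0.10, adjusted p = 0.0338).

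The mitochondrial ribosomal score of complicated against uncomplicated CVID was -0.53 ± 0.08 with LPS and -0.20 ± 0.08 in medium, where the median of the family was -0.18 (p = 0.0541 by limma's camera with an estimated correlation) and -0.09 without the run term. With LPS it was -0.50 ± 0.08 without the 4 shallowest libraries, -0.52 ± 0.07 within run 2, -0.50 ± 0.08 with T cell and monocyte scores as covariates, and -0.53 ± 0.08 with B cell and platelet scores. Depth and run left this difference nearly whole, as did the cell scores as covariates. LPS itself lowered the monocyte score, by a mean of -2.39 in complicated and -3 in uncomplicated CVID. In LPS cultures this covariate thus mixes response with monocyte share, and cannot decide whether that share plays a part. The cause of the difference stays open. The class of the patients, their treatment and their age were not told apart here.

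The B cell score of complicated CVID in medium was -2.61 ± 0.70 against healthy donors, -3.44 ± 0.67 within run 3, which held 2 of the patients, and -1.74 ± 1.54 within run 1. The switched memory B score was -3.62 ± 0.63, and -1.62 ± 0.41 with the B cell score as covariate. A lower share of B cells could therefore account for part of the fall in switched immunoglobulin genes, and a lower share of switched cells among them remains open. Bulk counts cannot separate the 2, and cell counts were not used here.

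The greater chemokine response of complicated CVID over healthy donors was 2.10 ± 0.65. It was 1.83 ± 0.78 without the 4 shallowest libraries, 2.46 ± 1.39 within run 3 and 2.63 ± 0.52 within run 1. In the LPS cultures themselves the difference was 0.57 ± 0.54, while in medium it was -1.53 ± 0.54. A higher chemokine level in the healthy donors' medium cultures may thus be a source of the response difference, which the data leave open.

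Splits of the donors into other groups of the same sizes were fitted in the same way, 100 for each comparison of classes. No other split reached the real count for complicated CVID against healthy donors in medium (337 genes, highest other split 11) or with LPS (337, highest other 50). The same held for complicated against uncomplicated CVID with LPS (1568, highest other 855). These splits mixed the runs, so 100 splits were also made within runs. The share of splits with as many genes stayed under 0.05, which made chance less likely but did not exclude it. Other splits gave more genes for complicated CVID against healthy donors in medium (3 of 100 splits with as many, the real one included, highest other 444) and with LPS (2 of 100, highest other 677). Both highest splits kept 8 of the 9 patients together. The complicated patients of run 2 could not move, since that run held no healthy donors. For complicated against uncomplicated CVID with LPS 1 of 100 splits had as many, the highest other split within runs giving 408. Only the patients of run 2 could move there. For uncomplicated CVID against healthy donors with LPS (12, highest other 3) no other split keeps the runs, so chance and the runs cannot be told apart there. The splits say nothing about chance where edgeR called 0 genes, since all 100 splits reach that number whatever the data. This was so in medium for uncomplicated CVID against healthy donors (1413 genes at an unadjusted p under 0.05, 84 with DESeq2, highest other split 52) and for complicated against uncomplicated CVID (1381, 6 with DESeq2, highest other 51), and for the 3 differences of response without a block (1071, 151 and 1068 genes at an unadjusted p under 0.05, 64, 0 and 0 with DESeq2, highest other 0). With donor as a block, 40 splits were fitted, and no other split called a gene for complicated CVID against healthy donors (5 genes, highest other 0) or against uncomplicated CVID (12 genes, highest other 0). These splits mixed the runs and none were made within runs, so that chance was not excluded there.

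For LPS against medium the real split was compared with splits that also parted every donor's 2 libraries. No other split reached the real count in healthy donors (1723 genes, highest other 794) or in complicated CVID (4195, highest other 2482), each over 60 splits. In uncomplicated CVID the 16 such splits were too few for a share under 0.05 (1713, highest other 1117). Another 40 splits in each class left some donors' libraries together, and gave at most 900, 82 and 465 genes in healthy donors, complicated and uncomplicated CVID.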
